A study of Arabidopsis thaliana with 33 samples.

How the data were processed

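Flowers of 3 Arabidopsis thaliana mutants were compared with wild type on 33 long-oligonucleotide arrays, each hybridised with mutant RNA in one dye (Cy3 or Cy5) and wild-type RNA in the other. Per the labels' protocols, total RNA came from tissue of 50 plants per sample, was amplified to antisense RNA and was coupled to the dyes. The ap3, nzz and ms1 mutants had 4 arrays each, 2 in each dye orientation. The ms1 series had 7 stage samples of 3 arrays each, one from each of 3 sets collected on different days, with the mutant in Cy3 in sets 1 and 3 and in Cy5 in set 2. Per the labels, at least 3 independent biological samples were used, with the dyes switched between replicates. That wording does not settle whether all 4 arrays of a mutant came from separate samples. Groups and dyes were taken from the labels alone.

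The authors deposited 1 normalized table, and its values were read here as log10 ratios of the 2 RNAs on each array. The base is inferred and not stated: no value lies beyond -2 or 2, which base 10 makes a limit of 100-fold. With base 2 the limit would be 4-fold, and every log2 value given here would be 3.32 times too large, while calls without a fold threshold would not change. The scanner software, background correction and normalization are not given in the sources used here. The medians of the arrays lay between -0.042 and 0.0253 in the deposited unit, so the arrays had been centred near 0; as log2 ratios of mutant over wild type the medians lay between -0.08 and 0.14. Of 26540 lines, 26090 were gene probes and 450 controls (430 of them empty spots), which were left out of the tests. An array had 31 to 1328 missing values (median 76). Between 2.37% and 17.7% of an array's values (median 3.74%) lay at the limit, where a ratio is a bound and has no measured size. The number of arrays, not a count depth, limits the precision.

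Which RNA is the numerator is not stated. A rule fixed in advance was to read from the correlation of replicate arrays with opposite dyes whether the values are dye ratios or already turned to one direction. Over all gene probes these correlations were negative (r = -0.734 for the means of the orientations), which read literally makes the values dye ratios. That literal reading was departed from after the data had been seen. Of the values at the limit, 97.4% pointed in the direction of the dyes, as did 98.7% of the limited values of the empty spots, and 66.3% of all empty-spot values were at the limit. Over the 16600 gene probes never missing or at the limit, r was -0.03. There, the deviations of replicate arrays from the means of their orientation were positively correlated in 22 of 26 pairs with opposite dyes (median r = 0.24, against -0.01 between groups). The values were therefore read as already turned, with a dye effect fitted as a term. The evidence was uneven: over those probes, replicate arrays with opposite dyes gave r of 0.50 to 0.57 in nzz, 0.10 to 0.27 in ms1, -0.11 to 0.06 in ap3 and -0.61 to -0.04 in series sample 1.

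The sign was chosen after the data had been seen as well. The titles name the mutant before wild type, which could be taken as mutant over wild type, but positive deposited values were read as higher in wild type. The basis is the study's stated design, in which ms1 lacks viable pollen and genes of sporogenous tissue were expected to be lower in nzz, together with the side on which genes of mature pollen lie. The 8 measured meiosis genes did not favour this sign in nzz: their median was 0, and the 1 called gene was higher under it. The chosen direction is likely, not settled. The fall of pollen genes is thus part of the reason for the sign and no independent result. With the opposite sign every "lower" and "higher" would change places, and no count of calls would change. Arrays of the same dye orientation correlated at r = -0.09 or above. Values were multiplied by the log2 of 10 and turned, so that negative log2 ratios mean lower in the mutant.

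Probes were named through the platform's annotation, updated by gene identifier with the RefSeq gene table of assembly TAIR10.1. It named 13960 probes with 1 gene each and no probe with several, and 13912 of them had a current locus (13698 loci, 210 of them with several probes). The other 12130 gene probes are unnamed here and entered the tests and counts.

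The main test was limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0), with lmFit and eBayes, 1 coefficient per group and 1 dye term per probe. The 12 mutant arrays were fitted together, and so were the 21 series arrays. A probe was tested in a group with at least 3 of 4 values (mutants) or 2 of 3 (series), and was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes tested. The dye term passed the same threshold at 5225 probes in the mutants and 7184 in the series. In the series this term also separates set 2 from sets 1 and 3, so dye and set cannot be told apart there. Errors of log2 ratios are SEs from limma, with 4 arrays per mutant and 3 per series sample unless stated. All adjusted p-values of probes come from limma. The difference between the ms1 and nzz ratios was tested as a contrast, and differences between the 7 series samples with an F test. In the simulated data, 24698 mutant probes had 200 changed. The fit recovered 58 of 100 changes of 1 log2 unit in ap3, 62 in nzz and 71 in ms1, and 77 of 100 changes of 2 log2 units in each, with 4 false calls each. In series sample 1, simulated on 23323 probes, it recovered 49 of 100 and 66 of 100, with 7 false calls. In series sample 5 it recovered 46 of 100 and 73 of 100, with 10 false calls among 129. Unlike the real data, the simulated noise was independent between arrays, and no values were missing or limited.

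The groups, the main tests, the first set of alternatives, the naming rule and the 16 gene lists were fixed before the data were examined. The lists hold 250 loci, of which 56 had a probe. They cover B and C class floral organ identity, early anther and sporogenous cell regulators, tapetal transcription factors, tapetum and pollen wall biosynthesis, pollen coat proteins, meiosis, mature pollen and pollen tube, pollen transcription factors, jasmonate and late stamen maturation, carpel and ovule, nectary, meristem and organ boundary, photosynthesis in green organs, mitotic cell cycle, flavonoid biosynthesis, and defence and abiotic stress. Lists with at least 3 complete probes were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. The naming rule takes the mutated genes, the 12 most negative and 8 most positive called genes per mutant (3 and 2 per series sample) with the same sign on every array, and up to 4 members of each list with the largest ratios, plus any called member. For several probes of a gene the one with the lowest p was named. Genes named outside this rule are marked.

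Alternatives were median centring, scaling of the spread, no dye term, the replicate or set number as a block, leaving out each replicate, complete probes, averaged probes, a robust prior, a 2-fold threshold and a fit of each group alone. Treating limit values as missing, leaving out limited probes, reading the values as dye ratios and leaving out single doubted arrays were added after the data had been seen. Sets pair the series arrays, because the labels tie sets to days; as a block, the set takes the place of the dye term, since each set has 1 dye orientation. The residuals of arrays of one set had a median r of 0.20 (over 0.1 in 41 of 63 pairs), against -0.06 between sets. Random draws of gene positions numbered 10000, and other groupings of the arrays were refitted at most 100 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.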

Results

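The arrays compared flowers of 3 male-sterile or stamen-deficient mutants with wild type, to find genes active in successive phases of stamen development. AP3 is a floral homeotic gene needed for petals and stamens, SPL/NZZ is needed to start sporogenesis, and MS1 is needed in the tapetum, the nurse tissue of the anther. For ap3, the inflorescence meristem and young buds were collected (4 arrays). For nzz and ms1, the meristem and all buds up to flower maturity were collected (4 arrays each). A separate ms1 series split flowers by age into 7 samples of 3 arrays each, with sample 1 described as mature flowers and sample 7 as the youngest buds with the meristem. Of the mutated genes, only SPL had a named probe. In nzz its log2 ratio was -0.26 ± 0.12 (SE, n = 4 arrays), with an adjusted p of 0.174 from limma. Where this probe lies relative to the mutation is not given, so it does not check the labels. Here and below, negative ratios mean lower in the mutant. That direction is likely but not settled, since the deposited values do not state it, and the opposite sign would exchange every "lower" and "higher".

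In ap3 early buds, a small group of genes fell and fewer rose. Among called named genes with 1 sign on every array, the lowest ratio was that of AT1G44970, at -3.57 ± 0.29 (11.9-fold lower, adjusted p = 0.0026). VGD1, a pectin methylesterase of the pollen tube, fell by 2.36 on the log2 scale (SE 0.35, adjusted p = 0.0485). THI2.1, a thionin, was 2.84-fold lower (-1.51 ± 0.20, adjusted p = 0.0323). The highest among these was that of AT4G26280, at 1.41 ± 0.12 (adjusted p = 0.00419), followed by ARR15, a response regulator of the cytokinin pathway, at 0.99 ± 0.11 (adjusted p = 0.0176).

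Other genes lower in ap3 on all 4 arrays were AT3G07820 (-2.84), AT5G39880 (-2.80), AT1G23350 (-2.62), AT1G33430 (-2.62) and AT1G73890 (-2.40). AT3G18900 stood at -2.41 ± 0.12 on the probe with the lowest p, but its other probe read 0.04 ± 1.44. AT2G43620, AT2G28140 and AT5G62360 fell by 1.38, 1.06 and 1.04, and AT5G43690, AT3G15720, UGT74D1, AT2G27240 and AT3G07470 rose by 0.77, 0.74, 0.67, 0.52 and 0.45. By limma, 46 of 26017 probes were called, 32 lower and 14 higher, and 28 of them were named. The medians of these calls were -1.40 and 0.81. The count was 18, 10, 10 and 24 without replicates 1 to 4 in turn, 24 without the dye term, 6 with the replicate number as a block, and 272 with the arrays scaled to one spread. With the 4 arrays fitted alone in limma, no probe passed (1753 at an unadjusted p under 0.05). Of 19 calls on named genes, 4, 3, 3 and 5 were kept without these replicates in turn, and that of VGD1 was lost each time and after centring. Read as dye ratios, the values gave 514 calls.

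Tapetal transcription factors stood lower in ap3 buds as a list, although none of the 4 measured members passed the test alone. All 4 passed when adjusted over the list alone. The ratios were -2.63 ± 0.54 for bHLH091, -2.37 ± 0.86 for bHLH089 (1 array at the limit of -6.64, another at 0.22), -1.40 ± 0.61 for AMS and -1.23 ± 0.29 for bHLH010, all of them bHLH regulators of the tapetum. Without replicate 1, AMS stood at -0.44 and bHLH010 at -0.78. The camera adjusted p was 4.71e-05 (adjusted p = 0.068 with an estimated correlation). Of 9 mature pollen genes, only VGD1 fell, with VGDH1 at -2.49 ± 0.41 (adjusted p = 0.0776). Adjusted over the list alone, 2 were lower, and the camera adjusted p was 0.000186 (adjusted p = 0.068 with an estimated correlation). The early anther regulators had 0 of 5 members called and 3 lower when adjusted over the list alone, with ROXY2 at -3.54 ± 1.07 (1 array at the limit of -6.64, another at -0.07) and SPL at -0.47 ± 0.12. Their camera adjusted p was 0.0137 (adjusted p = 0.068 with an estimated correlation). The tapetum and pollen wall list, with a median of -1.11 over 4 genes, gave a camera adjusted p of 0.0492 (adjusted p = 0.166 with an estimated correlation). It passed neither with fry (adjusted p = 0.111) nor after centring (adjusted p = 0.0679).

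Photosynthesis genes stood slightly lower in ap3 (LHCB4.1 at -0.29 ± 0.13, RCA at -0.15 ± 0.16) and flavonoid genes higher (DFR at 1.37 ± 0.60). Their camera adjusted p-values were 0.0286 and 0.0182 (adjusted p = 0.209 and adjusted p = 0.091 with an estimated correlation). The photosynthesis test used 3 probes of only 2 genes. That list did not pass with fry (adjusted p = 0.111), while the flavonoid list did (adjusted p = 0.0304). No member of either list was called. Meiosis genes had a median of -0.07 over 8 members and pollen transcription factors 0 over 7, with camera adjusted p-values of 0.821 and 0.474. Defence and abiotic stress genes had a median of 0.05 over 4 members (camera adjusted p = 0.41). Adjusted over the list alone, CLV3, a meristem signal (0.57 ± 0.15), SPT, a carpel regulator (0.42 ± 0.08), 1 of 2 mitotic genes and 1 of 3 flavonoid genes were higher. Likewise 1 of 2 nectary genes and 1 of 4 stress genes were lower. None of these was called over all probes. CLV3 was the only measured gene of its list, so its p-value was in effect unadjusted, and SPT was 1 of 2 in its list.

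Genes of the tapetum and of pollen were far lower in nzz inflorescences, where sporogenesis fails. AMS, a tapetal transcription factor, stood at -5.32 ± 0.61 (40.1-fold lower, adjusted p = 0.000867) and ATA27, an anther gene of the tapetum, at -6.22 ± 0.86 (adjusted p = 0.00231), with 1 and 2 of 4 arrays at the limit. ACT12, an actin of pollen, stood at -4.14 ± 0.20 (adjusted p = 3.16e-05) and VGDH1, a relative of VGD1, at -5.09 ± 0.41 (adjusted p = 0.000188). SDS, a cyclin-like protein of meiosis, rose by 0.49 ± 0.09 (adjusted p = 0.0101).

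Among called genes with 1 sign on every array, the most negative in nzz were AT3G62710, at the limit of -6.64 on all 4 arrays, AT3G01270 (-6.31 ± 0.47), AT3G01240 (-6.08 ± 0.54) and AT1G30350 (-6.05 ± 1.02), the last 3 with 2 arrays at the limit each. AT1G26720, AT1G30020, AT1G47980, AT1G23240, AT1G06260 and AT5G38760 lay between -5.77 and -5.18. The most positive of these rested on limited values. AT2G12880 was at 6.64 on 4 of 4 arrays, AT1G20730, AT1G33870 and AT1G70080 on 3 of 4, and AT3G55940, AT3G29791, AT5G42850 and AT1G44050 on 2 arrays each. For AT1G20730 the other probe was called with the opposite sign (-2.93 ± 0.83, adjusted p = 0.0438).

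By limma, 3967 of 26046 probes were called in nzz, 1801 lower and 2166 higher, 2111 of them named. The lower calls had a median of -0.92 and the higher calls 0.40, and at least 2-fold changes numbered 847 lower and 121 higher. Array medians in nzz lay above 0 on all 4 arrays (0.02 to 0.13 log2 units). After each array was centred on its median, 3047 probes were called, 2117 lower and 930 higher, so that 30.5% of calls were higher in place of 54.6%. That share was 49.9% with the arrays scaled to one spread, 44.1% without the dye term and 31.1% to 49.7% without 1 array, so which direction had more calls was not stable. Without replicate 1 the count was 1464, without replicate 2 it was 1758, without the dye term 2403, and with values read as dye ratios 742. Of 35 or 36 calls on named genes, 22, 23, 25 and 26 were kept without replicates 1 to 4 in turn.

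Of 9 mature pollen genes, 5 fell in nzz (VGDH1, ACT12, VGD1 at -4.02 ± 0.35, LRX8 at -3.41 ± 0.69 with 1 array at the limit and ANX1 at -2.13 ± 0.62), and 6 were lower when adjusted over the list alone. The camera adjusted p was 2.25e-07. Of 4 tapetum and pollen wall genes, 3 fell, both over all probes and adjusted over the list alone (ATA27, SHT at -5.01 ± 1.34 with 1 array at the limit and ATA20 at -4.46 ± 0.51, camera adjusted p = 0.00151). UNDEAD stood at -0.13 ± 0.86. Of 7 pollen transcription factors, AGL104 (-2.07 ± 0.35), AGL18 (-1.21 ± 0.15) and AGL66 (-1.13 ± 0.14) fell, as they did adjusted over the list alone (camera adjusted p = 0.00274). These 3 list calls held with an estimated correlation (adjusted p of 0.03, 0.043 and 0.043).

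Of 4 tapetal transcription factors, 3 fell in nzz, also adjusted over the list alone. They were AMS, bHLH091 (-2.43 ± 0.54) and bHLH010 (-1.19 ± 0.29), and the list had a camera adjusted p of 0.00112 (adjusted p = 0.0961 with an estimated correlation). Of 5 early anther regulators only EMS1, a receptor kinase that specifies the tapetum, fell (-0.55 ± 0.08, adjusted p = 0.00366), again adjusted over the list alone as well. That list had a camera adjusted p of 0.046 (adjusted p = 0.0961 with an estimated correlation), and 0.0929 after centring. Of 2 pollen coat genes, EXL5 fell (-4.33 ± 0.59), and EXL2, at 0.66 ± 0.26, was higher only when adjusted over the list alone. Of 8 meiosis genes SDS alone rose and the list's camera adjusted p was 0.903. KIN1, a cold-induced gene of the stress list, fell (-1.14 ± 0.18, adjusted p = 0.00415) among 4 members. That list did not pass with camera (adjusted p = 0.114) but passed as lower with fry (adjusted p = 0.0092). Photosynthesis (median -0.20) and flavonoid genes (median 0.67) had no member called and camera adjusted p-values of 0.286 and 0.828.

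Genes of mature pollen fell in ms1 inflorescences too, while tapetal regulators did not pass the test. VGDH1 fell by 4.22 (SE 0.41, adjusted p = 0.00183), VGD1 by 3.43 (SE 0.35, adjusted p = 0.00192) and ACT12 by 2.69 (SE 0.20, adjusted p = 0.00119). EXL5, of a lipase family that includes pollen coat proteins, fell by 3.40 (SE 0.59, adjusted p = 0.0217). AMS stood at 1.17 ± 0.61 (adjusted p = 0.415). A smaller group rose, among them AT1G54540 at 3.06 ± 0.61 (8.35-fold, adjusted p = 0.0368) and AT1G13910 at 2.66 ± 0.27 (6.33-fold, adjusted p = 0.00203), both higher on 4 of 4 arrays with none at the limit.

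Among called genes with 1 sign on every array, the most negative in ms1 were AT3G62710 (-5.46 ± 0.65, at the limit on 3 of 4 arrays), AT3G01270 (-5.19 ± 0.47) and AT3G28820 (-5.11 ± 0.59). AT1G26720, AT3G01240, AT3G28780, AT3G07820, AT1G11765, AT1G47980, AT1G23240 and AT3G54800 lay between -4.71 and -4.20. The other most positive of these were AT4G20420 (2.56 ± 0.42), AT5G02540 (2.52 ± 0.51), AT5G59490 (2.07 ± 0.42), AT1G03390 (2.01 ± 0.38), AT2G22510 (1.82 ± 0.26) and AT1G09880 (1.79 ± 0.25). By limma, 567 of 26039 probes were called, 454 lower (median -1.51) and 113 higher (median 0.76), 312 of them named. At least 2-fold changes numbered 309 lower and 43 higher. Read as dye ratios, the values gave 729 calls, 403 lower and 326 higher. The count was 278 without replicate 2, 217 without replicate 3, 768 without replicate 4 and 273 with the replicate number as a block, and no probe passed in limma when the 4 arrays were fitted alone without the dye term (1529 at an unadjusted p under 0.05). Of 25 calls on named genes, 18, 16, 13 and 20 were kept without replicates 1 to 4 in turn.

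Of the 9 mature pollen genes, 4 fell in ms1 (VGDH1, VGD1, ACT12 and ANX1 at -3.07 ± 0.62 with 1 array at the limit), 7 were lower when adjusted over the list alone, and all 9 ratios were negative. The camera adjusted p was 6.27e-10, and 0.0118 with an estimated correlation. Of 7 pollen transcription factors AGL66 fell (2-fold, adjusted p = 0.00711) and 2 were lower when adjusted over the list alone, with a camera adjusted p of 0.00821 (adjusted p = 0.0673 with an estimated correlation). No tapetum and pollen wall gene passed over all probes, and 1 of 4 did when adjusted over the list alone. ATA27 stood at -3.91 ± 0.86 (adjusted p = 0.0591) and SHT at -3.54 ± 1.34, with a camera adjusted p of 0.011 (adjusted p = 0.0946 with an estimated correlation). The tapetal transcription factors had a median of 0.33 over 4 genes, the early anther regulators -0.11 over 5 and the meiosis genes 0.14 over 8, with camera adjusted p-values of 0.795, 0.923 and 0.795. Photosynthesis (median 0.05), flavonoid (median 0.15) and stress genes (median 0.16) each had a camera adjusted p of 0.923 and no member called.

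Other lists had fewer than 3 complete probes, too few for a list test. The B and C class list had no probe. In ap3, nzz and ms1 in turn, the jasmonate list's 1 gene, ADPG1, stood at 1.18 ± 1.15, -2.48 ± 1.15 and -1.21 ± 1.15. The nectary sugar transporter SWEET9 stood at -0.40 ± 0.70, -2.14 ± 0.70 and -1.41 ± 0.70. The carpel and ovule list had medians of 0.18, 0.25 and 0.16 over 2 genes, the mitotic kinases AUR1 and AUR2 medians of 0.22, 0.20 and 0.07, and CLV3 ratios of 0.57, 0.02 and -0.14. No member of these lists was called in the 3 mutants.

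**Figure D1:**
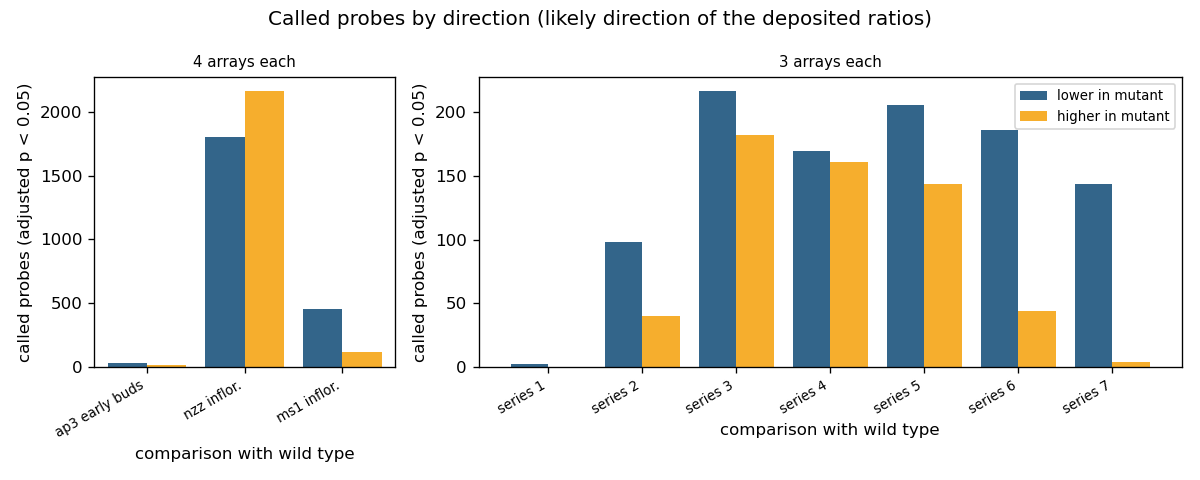
Bars give the number of probes called by limma at an adjusted p under 0.05 as lower (blue) or higher (orange) in the mutant, for the 3 mutants (left axis, 4 arrays each) and the 7 ms1 series samples (right axis, 3 arrays each, labelled series 1 to 7). The nzz bars reach 1801 lower and 2166 higher probes, ap3 46 in total, and series sample 1 only 2.

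The overlap asked which genes the 3 mutants shared. AT3G07820, AT5G39880, AT1G23350 and VGD1 were lower in all 3, the only 4 probes to be so. Of the 454 probes lower in ms1, 419 were also lower in nzz, where independent lists would share 31.4. Of 113 higher in ms1, 19 were higher in nzz (9.41 for independent lists), and 16 called lower in nzz were called higher in ms1. Of 32 lower in ap3, 15 were lower in nzz (2.22 for independent lists) and 4 in ms1 (0.56). The labels do not say whether arrays shared wild-type RNA, and part of an overlap could come from a shared control. The 3 mutants also shared 1 fit, with 1 spread and 1 dye term per probe. Their calls are therefore not independent, which can add to an overlap.

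The ms1 and nzz ratios themselves differed for AMS, the only 1 of 4 tapetal transcription factors to pass, and for EMS1. Of the 23 genes in the tapetum and pollen wall list only 4 were measured, and none of these passed. AMS was higher in ms1 than in nzz relative to wild type by 6.49 ± 0.86 log2 units (adjusted p = 0.0165, with 1 nzz array at the limit), and EMS1 by 0.81 ± 0.12 (adjusted p = 0.0233). Among the genes most raised in ms1, AT1G54540 differed by 5.58 ± 0.86, AT4G20420 by 4.20 ± 0.59, AT1G13910 by 3.27 ± 0.39 and AT1G09880 by 3.05 ± 0.35, and all 4 had negative ratios in nzz (-2.52, -1.64, -0.61 and -1.26). AT5G38760 was negative in both, at -2.09 in ms1 and -5.18 in nzz. SWEET8, a sugar transporter needed for pollen wall formation, and BGAL15, a beta-galactosidase, were chosen after their values were seen. They differed by 4.49 ± 0.56 and 5.08 ± 0.24.

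By limma, the difference passed at 178 of 26004 probes, 170 of them with the higher ratio in ms1 and 8 with the higher ratio in nzz. Of the 178, 154 were called lower in nzz, 8 of these were also lower in ms1 and 16 were higher there. In 111 the ratios had opposite signs. Leaving out any 1 of the 8 arrays brought the count to between 35 (without nzz replicate 1) and 113 (without ms1 replicate 4): without ms1 replicates 1, 2 and 3 it was 52, 95 and 72, and without nzz replicates 2, 3 and 4 it was 77, 77 and 69. With the replicate number as a block 9 probes differed, with the arrays scaled to one spread 81, and with limited probes left out 347. Read as dye ratios, the values gave 27 differences, 14 with the higher ratio in ms1 and 13 with the higher ratio in nzz.

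The ms1 series asked when in flower development ms1 departs from wild type. Sample numbers are those of the labels. The median of the mature pollen genes was lowest in the samples labelled 6 and 7, but the called members ACT12 and VGDH1 were lowest in sample 5 (-3.75 and -5.17). VGD1 stood at -4.20 ± 0.32 in samples 5 and 6 and -3.73 ± 0.32 in sample 7, against -0.60 ± 0.32 in sample 1 (adjusted p of 1.12e-05, 1.89e-05, 5.47e-05 and 1). EXL5 stood at -5.50, -5.81 and -5.39 in samples 3, 4 and 5 (SE 0.90, 3 arrays each), and at -0.20 on 2 arrays of sample 7. The bHLH regulator bHLH010 fell in the same 3 samples, by 0.88, 0.97 and 0.86 (SE 0.15), while AMS and bHLH091 had positive ratios there and were not called. Sample 1 was described as mature flowers, where mature pollen would be found, and only 1 named gene was called in it.

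Mature pollen genes as a list gave no call in the sample labelled 1 (median -0.14 over 9 genes, camera adjusted p = 0.989). In samples 6 and 7, all 9 ratios were negative, with medians of -2.56 and -2.45, and camera adjusted p-values of 8.99e-19 and 1.36e-23. Over all probes 4 and 3 members were called, and 8 in each when adjusted over the list alone. They included ACT12 (-3.53 and -3.34, SE 0.33) and VGDH1 (-5.01 and -4.65, SE 0.95), and in sample 6 LRX8, a leucine-rich repeat extensin (-4.23 ± 0.83, 1 array at the limit). In samples 4 and 5, 2 and 3 members fell (3 and 3 adjusted over the list alone) and camera gave adjusted p-values of 0.000297 and 0.000235 for a lower list, although the medians of 0.04 and 0.20 were positive. ACT12 was called from sample 2 (-1.75 ± 0.33) and sample 3 (-2.73 ± 0.33) on, where the list's camera adjusted p-values were 0.237 and 0.289. The calls of samples 4 to 7 held with an estimated correlation (adjusted p of 0.0192, 0.0175, 1.24e-05 and 3.29e-06).

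Pollen transcription factors were lower in samples 5, 6 and 7, with medians of -0.60, -0.60 and -0.56 over 7 genes and camera adjusted p-values of 0.00215, 0.00341 and 0.000468. These held with an estimated correlation (adjusted p of 0.0185, 0.0235 and 0.00884). AGL66 was the member called over all probes, in samples 6 (-1.58 ± 0.24) and 7 (-1.54 ± 0.24), and 3, 3 and 4 members passed when adjusted over the list alone. With the set as a block, AGL18 was also called in samples 6 (-0.65, adjusted p = 0.0394) and 7 (-0.85, adjusted p = 0.0108), AGL104 in sample 5 (-1.90, adjusted p = 0.0247) and LRX8 in sample 7 (-4.30, adjusted p = 0.0288). In samples 1 to 4 the list's camera adjusted p was 0.989, 0.788, 0.589 and 0.703.

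The tapetum and pollen wall list had medians of -2.20, -2.30, -2.13 and -2.17 over 4 genes in samples 2 to 5, against 0.30 and -0.37 in samples 6 and 7. In sample 1 its arrays disagreed, with medians of -0.05, 1.97 and -3.68 in sets 1 to 3. No member was called over all probes. ATA27 stood at -5.02, -4.85, -3.99 and -3.89 in samples 2 to 5 and SHT at -3.98, -4.49, -4.50 and -3.17 (SE 1.74). The highest member stood at 0.24, 0.23, -0.01 and -0.16 there. The medians thus lay between genes far apart and do not measure a fall shared by all 4. Camera adjusted p-values were 0.0319, 0.0759, 0.0202 and 0.00444, and 1, 2, 2 and 1 members passed when adjusted over the list alone. Those of samples 2 and 4 were lost with an estimated correlation (adjusted p = 0.106 and adjusted p = 0.0613 with an estimated correlation), and that of sample 5 was kept (0.0213). Both were also lost with fry (adjusted p = 0.0851 and adjusted p = 0.0774), and that of sample 2 after centring (camera adjusted p = 0.0699). In samples 1, 6 and 7 camera gave 0.989, 0.981 and 0.227. AMS stood at 2.01, 2.03, 1.69 and 1.88 in samples 3 to 6 (SE 0.58, not called over all probes) and was called at -4.32 ± 0.70 in sample 7, on 2 arrays of which 1 was at the limit. Of the 4 tapetal transcription factors, 2, 2, 1 and 1 were higher in samples 3 to 6 and 2, 2, 2 and 0 lower when adjusted over the list alone.

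Among the other lists of the series, UGT78D2, a flavonoid glycosyltransferase, fell in sample 2 (-1.74 ± 0.34, adjusted p = 0.0289). The flavonoid list's camera adjusted p there was 0.188, and 0.0183 with the set as a block. In sample 3, UGT78D2 passed with that block alone (-1.21, adjusted p = 0.000924). The mitotic kinases AUR1 and AUR2 had medians of -0.76 and -0.85 in samples 6 and 7. Both passed when adjusted over the list alone and neither over all probes, while AUR1 passed with the set as a block (-0.79, adjusted p = 0.00489, and -0.77, adjusted p = 0.00721). Early anther, meiosis, photosynthesis and stress lists gave no camera call in the series. Medians ranged from -0.10 to 0.43 for the first, -0.17 to 0.09 for meiosis, -0.17 to 0.14 for photosynthesis and -0.27 to 0.24 for stress genes. No member of the carpel, nectary, meristem and jasmonate lists was called.

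**Figure D2:**
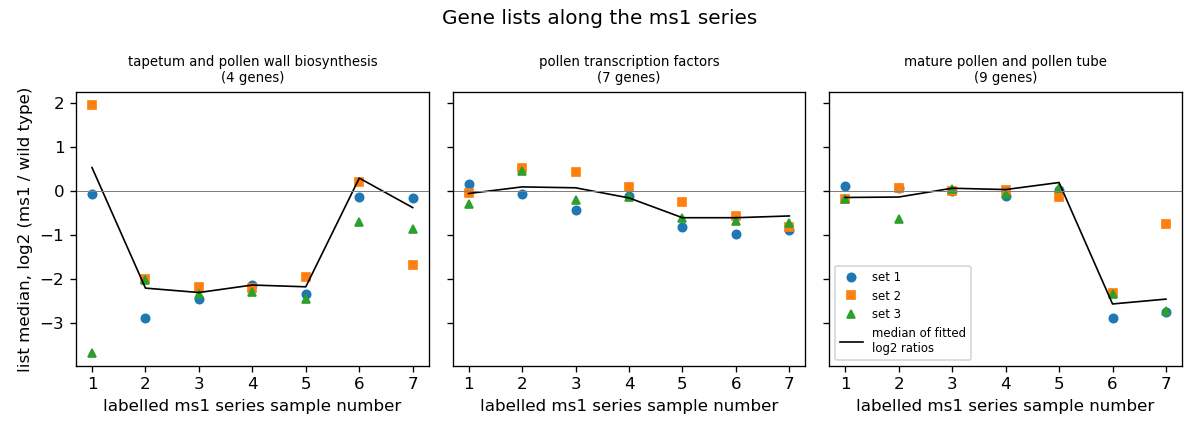
Points give the median log2 ratio (ms1 over wild type) of 3 gene lists on each array, by labelled series sample number, with a marker for each of the 3 sets, and lines join the medians of the fitted ratios. The median of the tapetum and pollen wall list lies near -2.20 in samples 2 to 5, between members far apart. That of the mature pollen list reaches -2.56 and -2.45 in samples 6 and 7.

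Among called genes with 1 sign on every array, AT3G01240 and AT3G01270 led samples 5, 6 and 7 (AT3G01240 at -5.88, -5.55 and -6.05, SE 0.58, and AT3G01270 at -5.90, -6.28 and -5.96, SE 0.66), with AT3G28750 at -5.34 and -5.13 in the last 2 and AT1G23240 at -5.48 ± 1.14 in sample 5. AT1G47980 and AT1G30020 led samples 2 (-6.06 and -5.57) and 3 (-5.85 and -5.61), with AT3G60650 at the limit on both arrays that measured it in sample 2. AT1G26720 stood at -5.65 ± 0.45 in sample 3, and AT1G26710 and AT1G06260 at -5.66 in sample 4. The highest ratios among these in samples 3 and 4 were those of AT2G19400, at the limit on every array that measured it, AT3G05920 (5.22, 1 array at the limit) and AT1G18960 (4.81 ± 0.81, none at the limit). AT1G72080 (4.62 ± 0.79, 2 of 3 arrays at the limit) and AT5G41400 (2.24 ± 0.34) rose in sample 2, AT5G26320 (4.27 ± 0.38) in sample 5, BGAL15 (4.72 ± 0.81) and AT3G59800 (3.33 ± 0.71) in sample 6 with 1 array at the limit each, and CSLB03 (adjusted p = 0.0164) and AT5G36160 (0.61 ± 0.11) in sample 7. AT5G26130 was called in sample 5 (4.80 ± 1.11, 2 arrays at the limit) and lost with the set as a block (adjusted p = 0.0693). In sample 1, AT5G41390 was at the limit on the 2 arrays that measured it.

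By limma, samples 1 to 7 had 2, 138, 399, 331, 350, 230 and 148 called probes. Of these 2, 98, 217, 170, 206, 186 and 144 were lower. With the set as a block samples 2, 5, 6 and 7 had 212, 544, 455 and 240, and with the set as a random block 115, 275, 164 and 125. Sample 1 had 915 probes at an unadjusted p under 0.05. Its count by limma was 0 without set 1 or set 3 (2142 and 1136 at an unadjusted p under 0.05), and 642 with the values read as dye ratios. It was 126 without set 2, where all arrays had the mutant in Cy3 and no dye term could be fitted. In sample 2, the array of set 2 had 17.7% of its values at the limit, and 55 probes were called without it. Leaving out the set 2 array of sample 3 (9.87% at the limit) gave 204 calls there, and leaving out the set 1 array of sample 7 gave 96. Other counts hung on whole sets. Without set 1, sample 2 had 73 calls, sample 3 256, sample 6 410 (214 lower and 196 higher) and sample 7 97 (75 lower and 22 higher); without set 2, samples 2, 3 and 4 had 59, 214 and 217; without set 3, samples 2 to 7 had 36, 196, 119, 57, 32 and 10. Of the calls on named genes, 25 of 51 were kept without set 1, 33 of 53 without set 2 and 11 of 50 without set 3.

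The effect of ms1 differed between the 7 samples at 352 of 25992 probes by the F test (30 without set 1, 202 without set 2 and 42 without set 3). Their largest change fell in samples 1 to 7 in 2, 22, 106, 83, 48, 50 and 41 cases. The probes lower in the separate ms1 inflorescence arrays had medians of -0.02, 0, -0.21, -0.50, -1.0, -1.48 and -1.27 in samples 1 to 7. Those higher there had medians of 0.06, 0.50, 0.87, 0.86, 0.67, 0.27 and 0.04. Across all probes, which are not independent replicates, the 2 collections correlated at r = 0.07, 0, 0.09, 0.22, 0.27, 0.24 and 0.23, and Spearman's rho was -0.01, 0, 0.01, 0.09, 0.12, 0.10 and 0.04.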

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

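The tests of the spots without signal, of the dye-ratio reading, of the precision of series sample 1 and of an exchanged array were chosen only after the results they test were seen; those of the sample numbering, of centring, of single arrays and of other groupings were written earlier. How the single-array test was to be judged was settled after its values were seen.

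The ms1 and nzz effects differed for 7 named genes in a direct test of the difference. Relative to wild type, AMS was higher in ms1 than in nzz by 6.49 log2 units (1 nzz array at the limit), AT1G54540 by 5.58, AT4G20420 by 4.20, AT1G13910 by 3.27, AT5G38760 by 3.09, AT1G09880 by 3.05 and EMS1 by 0.81. In all, 178 probes differed. In 35 splits of the 8 arrays into 4 and 4, only the real split (1 of 35) gave as many, and the highest other count was 24. Chance is thus unlikely for the count in this fit. It is not excluded, since 1 of 35 is the smallest share these splits can give. With the replicate number as a block 9 probes differed. Between the 7 ms1 series samples, 352 probes differed. Only the real assignment (1 of 100) gave as many, and the highest other count was 4. Chance is unlikely here too but not excluded, and the count was 30 without set 1.

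Some replicates lay far from the 3 others of their group. In ms1, replicate 2 stood alone at the limit of -6.64 for ROXY2, UNDEAD, ANX1, AGL30 and AGL94, at -0.95 for JAG (others 0.08 to 0.27) and at -0.88 for the median of the pollen transcription factors (others -0.36 to -0.28). This array had 9.99% of its probes at the limit. Replicate 1 of ms1 read -1.92 for AT3G62710, where the others were at -6.64, and -2.42 for AT3G07820. Replicate 3 read 2.99 for AT1G13910, and replicate 4 read 1.31 for AT5G59490 and 1.57 for AT1G03390.

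In nzz, replicate 3 was the one array not at the limit of 6.64 for AT1G20730 (1.95), AT1G33870 (1.61) and AT1G70080 (1.13), and the one array at the limit for AMS (-6.64, others -4.94 to -4.84). Replicate 2 read -1.01 for AGL18. In ap3, replicate 1 read -4.22 for ATA20 (others -0.45 to -0.25), -4.04 for the median of the tapetum and pollen wall list (others -0.42 to -0.03), 0.53 for AGL29 and 0.52 for AUR2. The fall of that list in ap3 thus lay mainly on 1 array. Replicate 2 read 0.99 for UGT78D2. Replicate 3 read 6.64 for JAG, 0.73 for PDF1.2 and -1.52 for AT5G62360, and replicate 4 read -3.53 for VGDH1. These are 26 values from tests of 183 named gene values and of the lists. Chance alone gives about 1 in 20 for normal values without a limit, a rate that does not apply to values at the limit. With 3 arrays at the limit the other is flagged by construction, as for AT1G20730, AT1G33870 and AT1G70080 in nzz and AT3G62710 in ms1.

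The median of the mature pollen genes moved most in series samples 6 and 7, although sample 1 was described as mature flowers. In a limma contrast, 5 of 9 mature pollen genes were lower in sample 7 than in sample 1, adjusted over the list alone, and 5 was exactly the bound set for this. The contrast takes 1 spread per probe from all 21 series arrays, so it does not measure the precision of sample 1 alone. The list medians of sample 1 were close, at 0.11, -0.17 and -0.18 in sets 1 to 3. For single genes, low precision in sample 1 stays open. A single exchanged array is argued against, since the list median was lower in sample 7 than in sample 1 in 3 of 3 sets. A reversed numbering of all samples stays open: the rank correlation of ap3 ratios with the mean sample number of the fall was -0.02 over 452 probes and decided nothing. A biological effect of stage also stays open and was not tested.

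Replicate arrays with opposite dyes were anticorrelated over all probes. This is consistent with spots that lack signal in one channel and are limited in the direction of the dye: over probes never at the limit r was -0.03, and 98.7% of the limited values of empty spots pointed in the dye direction. A reading of all values as dye ratios is argued against by the mature pollen list, in which 8 of 9 genes had 1 sign on both orientations in ms1 and nzz. That reading gave more calls in ap3 (514 against 46), series sample 1 (642 against 2), ms1 (729 against 567) and series sample 2 (140 against 138). It turns dye effects into calls by construction, so these counts decide nothing. The direction stays open to doubt, most of all in ap3 and series sample 1. There, replicate arrays with opposite dyes gave r of -0.11 to 0.06 and -0.61 to -0.04 over probes never missing or at the limit. No biological explanation was tested.

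More probes were called higher than lower in nzz, most of them by under 2-fold. Whether the centring of the deposited arrays made this cannot be told apart: 30.5% of calls were higher after each array was centred on its median, against 54.6% before, but all 4 array medians lay above 0, so centring lowers that share by construction. The test of a single array as the cause could not decide either. The share lay under 50% in 4 of 4 fits without 1 array (lowest 31.1%), so the test singled out no array. Fewer arrays can also call fewer small changes. A biological shift stays open and was not tested.

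Exchanging mutant and wild type on some arrays gave too few other groupings for a share under 0.05. Of 8 such groupings per mutant, 1 was as large, the real one, with 46 calls in ap3 (highest other 17), 3967 in nzz (highest other 15) and 567 in ms1 (highest other 15). Of 4 groupings per series sample, 3 were as large in sample 1, where the real count was 2 and the highest other 23. In the other samples 1 was as large, with 138 in sample 2 (highest other 4) and 399, 331, 350, 230 and 148 in samples 3 to 7 (highest other 0 each).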

How the results depend on the processing

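The alternatives on limited values, the reading as dye ratios and the removal of single doubted arrays were chosen only after the results were seen; all other tests of this kind were set earlier. No called value of a named gene changed sign after centring, without the dye term, with a block, without 1 replicate or set, with a group fitted alone or with limits set to missing; named genes were not followed under the other alternatives. The nzz calls, with 54.6% higher in the fit reported, had 30.5% higher after centring, 49.9% with scaled arrays and 44.1% without the dye term. Of 134 called values of named genes, 129 were also called after centring, 99 without the dye term, 102 with the replicate or set as a block and 22 with each group fitted alone. Of 112 such values still measured with limits set to missing, 109 were called. For the changes below the cause was not tested, except that a fold threshold calls less by construction. Fewer arrays or probes did not always call less. The count was 768 against 567 in ms1 without replicate 4 and 410 against 230 in series sample 6 without set 1. In ap3 it was 107 against 46 with limited probes left out.

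With each group fitted alone without the dye term, limma called 974 probes in nzz and 0 in ap3, ms1 and series samples 1 to 7 (1753, 1529, 117, 453, 1028, 1180, 1495, 873 and 804 at an unadjusted p under 0.05). At least 2-fold changes numbered 26 in ap3, 968 in nzz and 352 in ms1. Without the dye term ap3 had 24, nzz 2403 and series sample 1 had 1. With the arrays scaled to one spread ap3 had 272, series samples 1 and 2 had 1 and 84, and the difference of ms1 and nzz 81. The replicate or set as a block gave 6 in ap3, 273 in ms1, 212, 544, 455 and 240 in samples 2, 5, 6 and 7, and 9 for the difference. In sample 1, centring gave 4, complete probes 0 (limma, 749 at an unadjusted p under 0.05) and a random block 1. With limited probes left out, ap3 had 107, sample 1 had 1 and the difference 347. With limits set to missing, samples 5, 6 and 7 had 627, 492 and 342, and the F test 613.

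Read as dye ratios, the values gave 514 calls in ap3, 742 in nzz, 729 in ms1 (44.7% higher, against 19.9%), 642 and 140 in samples 1 and 2, 64, 45, 39, 76 and 47 in samples 3 to 7, 27 for the difference (51.9% higher in ms1, against 95.5%) and 12 for the F test. That reading turns dye effects into calls by construction. Without 1 replicate or set, counts ranged from 10 to 24 in ap3, 1464 to 2693 in nzz, 217 to 768 in ms1, 0 to 126 in sample 1, 36 to 73 in sample 2, 196 to 256 in sample 3, 119 to 244 in sample 4, 57 to 312 in sample 5, 32 to 410 in sample 6, 10 to 134 in sample 7, 35 to 113 for the difference and 30 to 202 for the F test. Leaving out 1 doubted array gave 55 in sample 2, 204 in sample 3 and 96 in sample 7.

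Of 24 list calls, 12 held with an estimated correlation. Shared calls fell from 463 to 297 at 2-fold. For ap3 and nzz, 8 lower and 2 higher calls were shared without the dye term, and 0 higher at 2-fold. For ap3 and ms1 these were 1, 0 and 0, and for nzz and ms1, 10 higher were shared without the dye term and 0 at 2-fold. Spearman's rho between the ms1 collections was -0.01, 0.09, 0.12, 0.10 and 0.04 in samples 1 and 4 to 7 (median over samples 0.04), against r of 0.07, 0.22, 0.27, 0.24 and 0.23. The number of arrays limits the precision.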

Other observations

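The test of genome neighbours was chosen only after the results were seen, and so were the genes named here. Genes low in nzz and not called in ms1 included BGAL15, a beta-galactosidase (-4.38 in nzz, 0.70 in ms1, difference 5.08 ± 0.24, adjusted p = 0.00013), and SWEET8, a sugar transporter of pollen wall formation (-4.21 and 0.27, difference 4.49, adjusted p = 0.0132). SWEET3 differed by 2.87 (adjusted p = 0.0485), AT1G18960 by 5.75 and AT5G26320 by 6.71 (1 array at the limit).

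In the order of the measured genes along the genome, genes lower in the mutants were next to each other more often than in random draws. Genes without a named probe were skipped and no distance was set, so other genes can lie between the members of a pair. In ms1, 247 genes made 11 neighbouring pairs, against a mean of 4.43 and a highest value of 14 in 10000 draws (permutation p = 0.0045). In nzz, 916 genes made 91 pairs, against a mean of 61.2 and a highest value of 89 (permutation p = 1e-04, the smallest the draws can give). Tandem copies of similar sequence could share signal on the array, and this was not tested.

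Of 28 gene families tested per mutant with camera, adjusted over the 3 mutants, only the bHLH family in ap3 passed (adjusted p = 0.027), and it did not with an estimated correlation (adjusted p = 0.853). Its members overlap with the list of tapetal transcription factors.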
